A study of Drosophila melanogaster with 3 samples.

How the data were processed

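Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of both sexes, collected 0 to 16 hours after egg laying, in 3 biological replicates. Per the labels, the embryos came from a transgenic line that carries the E(spl)mgamma-HLH protein with GFP at its C terminus, an antibody against GFP was used, and chromatin was sonicated to 200 to 800 bp. All 3 samples form 1 group. The labels name a possible control experiment and the deposited text records list a control behind each peak list, but that control was not analysed here.

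The deposited files were peak lists in narrowPeak layout for the dm6 and dm3 genome builds. Per the deposited text records, each replicate's list was called on that replicate's alignment against the control, and a pooled list was called on the alignments of all 3 replicates together. The lists prepared as input for the irreproducible discovery rate (IDR) step hold background regions beside peaks, per the labels the authors gave them. The reproducible set in dm6, which the authors named the optimal IDR thresholded peaks, was derived from the pooled list and the lists of all 3 replicates, per those records. The dm3 version was recorded as derived from the pooled list and the replicate 3 list. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. Column 7 of the deposited lists holds each peak's signal, a coverage-type value that was not normalized between lists. Column 9 holds the q-value of the peak on the −log10 scale as deposited, and its highest value was shared by many peaks of a list. Column 10 holds the offset of the summit from the peak start, as deposited. The p-value column was not assigned in the deposited files. Signal values belong to the authors' own peak calls and were used here only to order peaks within a list. The files hold no read counts, so the sequencing depth of each replicate is unknown, and the list of replicate 2 held 30000 peaks in both builds, a round length that can be a set limit of the calling step. Values differ between replicates in part through list length, and ranks from lists of different lengths were not read as change.

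All positions below are in dm6, 1-based. Genes came from Ensembl release 115 on assembly BDGP6.54 and sequence from the matching RefSeq genome, restricted to the 6 main arms X, 2L, 2R, 3L, 3R and 4. The dm3 lists were compared only with each other. The top peaks of a list are its 4524 peaks of highest signal, which is the size of the reproducible set. Peaks were called shared when the summit of a peak lay inside a top peak of the other replicate, and the share was compared with 1000 circular shifts of a list along the joined arms, one-sided. Agreement of ranks was Spearman's rho across reproducible peaks matched in both replicates, without a p-value because peaks are not independent replicates.

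Each summit was put in the first class that applied: promoter (within 500 bp of any transcription start site, TSS), 5' UTR, CDS, 3' UTR, intron or intergenic. The intron class holds every other position inside a gene, so it took in 35 summits (2.17% of the class) in exons of noncoding genes. Class shares were compared with 1000 circular shifts of the summits, two-sided. Motifs were sought on either strand in windows of 101 bp around each summit and in 1 flanking window per peak centred 500 bp away on a random side, with the exact two-sided McNemar test over peaks. The 20 fixed motifs were the 10 E-box hexamers, the 4 N-box hexamers CACNAG, CACGCG, GGCACGTG, the Su(H) site YGTGRGAA, GAGAG, CAGGTA and TATCGATA, and all 2080 hexamers were searched as a separate family. Ranks of peaks with and without a motif were compared by the difference of their median with 100000 permutations, two-sided, and by Wilson 95% intervals in 10 equal rank bins. A gene counted as having a peak when a reproducible summit lay in its body or within 1 kb upstream. For 15 gene lists the number of such members was compared with 10000 random lists of protein-coding genes of the same size, matched in 20 bins of that territory length, two-sided. Peaks per arm were given with exact Poisson 95% intervals and tested against the arm's share of protein-coding TSSs by the exact two-sided binomial test. Benjamini-Hochberg adjustment was made within each family of tests (6 classes, 20 motifs, 2080 hexamers, 3 motif ranks, 15 lists and 6 arms), and 0.05 was the threshold. Wilson and Poisson intervals cover counting error only.

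The gene lists were fixed before the data were examined, as were the tests and the alternatives not said to be chosen later. They were the E(spl) complex bHLH repressors, Bearded family, other bHLH-Orange repressors, proneural bHLH proteins, Notch pathway, sensory organ and neuronal genes, neuroblast and temporal factors, segmentation genes, Hox genes, mesoderm and muscle regulators, EGFR pathway, Wg, Hh, Dpp and JAK/STAT pathway, cell cycle genes, cytoplasmic ribosomal proteins, and odorant and gustatory receptors. BobB and BobC of the Bearded family had no match in the annotation, which left 2 listed symbols out. The rule for named genes, set at the same time, took every member with a peak from the E(spl), Bearded, proneural and Notch lists, the gene with the TSS nearest to each of the 10 highest peaks, and up to 4 members of each other list with the highest-ranked peak.

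The procedures were tested on simulated data. Shifted summits gave 2 false motif calls in 400 tests, and a motif planted in 1%, 2% and 5% of the 4524 windows was called for 7, 15 and 19 of 19 motifs. Shifting does not keep the lower GC content of real summits than of their flanks. These motif rates therefore do not cover false calls through base composition. In the class test, shifted summits gave 3 false calls in 120. Random gene lists gave 2 false calls in 1500. Lists with 60% of their members bound were drawn without regard to territory length. Recovery was 0 of 50 draws at a size of 7 genes, 6 of 50 at 18 genes and 50 of 50 at 92 genes. The arm test gave 4 false calls in 600, the rank test 1 in 20, and a rank shift planted in 100 peaks was recovered in 20 of 20 draws. The test of shared peaks gave 0 false calls in 20 shifted lists. Alternatives changed the size of the peak set, left out each replicate, and changed the overlap rule, the promoter distance, the window, the flank, the random expectation and the rule that assigns peaks to genes. Leaving out a replicate kept reproducible peaks whose summit lay in a top peak of both other replicates. These smaller sets still hold peaks, summits and signal called on all replicates together. A call lost in them can reflect fewer peaks. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.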

Results

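Binding of E(spl)mgamma-HLH, a basic helix-loop-helix (bHLH) repressor of the Hairy/E(spl) family encoded in the Enhancer of split complex downstream of Notch, was profiled by ChIP-seq against its GFP tag in whole embryos of 0 to 16 hours. There were 3 biological replicates of 1 group, and the depth of each is unknown. The dm6 lists held 23367 peaks in replicate 1, 30000 in replicate 2 and 24251 in replicate 3, background regions included. The replicate 2 list had this same round length in dm3, so it can be a set limit and not a count of sites. Of these, 5411, 12953 and 7087 had a q-value below 0.05. Median peak widths were 356, 400 and 370 bp, and the lists covered 8.06, 11.1 and 8.62 Mb. The authors' reproducible set held 4524 peaks, all with a q-value below 0.05, with a median width of 384 bp and a total of 1.44 Mb. Unless a replicate is named, values below refer to this pooled set and have no replicate error of their own.

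The strongest sites were the same genes in every replicate. The highest peak lay -25 bp from the TSS of Ugalt, which encodes a UDP-galactose transporter (X:2703674 to 2704104), and ranked 2, 1 and 1 in replicates 1 to 3. It was followed by promoter peaks at CG14100 (-98 bp), at px (-202 bp), at Chro (-108 bp), which encodes the chromodomain protein Chromator, and at the Polycomb group gene ph-p (-475 bp). An intronic peak near cbt, a Krüppel-like zinc finger gene, lay -1409 bp from its TSS and ranked 3 in each replicate. The remaining 4 of the 10 highest peaks were nearest to CG11050 (an intron, 1039 bp), the arginine methyltransferase gene Art3 (-123 bp), tara (intergenic, -3173 bp) and CenG1A (-111 bp). Negative distances are upstream. All 10 had ranks between 1 and 12 in each replicate.

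Replicates 1 and 3 shared more of their 4524 top peaks with each other than with replicate 2. Of the top peaks of replicate 1, 81.3% (Wilson 95% interval 80.1 to 82.4%) had their summit in a top peak of replicate 3 and 75.2% (74.0 to 76.5%) in a top peak of replicate 2. Of those of replicate 3, 81.0% were shared with replicate 1 and 76.4% with replicate 2. For replicate 2 the shares were 75.1% with replicate 1 and 76.7% with replicate 3. The mean over the 6 ordered pairs was 77.6% ± 2.80 (SD), against at most 2.19% in any shifted list. The one-sided permutation p was 0.000999 for each pair, the smallest that 1000 shifts can give. Over all listed peaks, background included, the mean share was 43.3%.

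Of the reproducible peaks, 3097 (68.5%) had their summit in a top peak of all 3 replicates, 1021 in 2, 385 in 1 and 21 in none. The share found among top peaks was 87.4% in replicate 1, 83.9% in replicate 2 and 87.8% in replicate 3. Across matched peaks, Spearman's rho of the signal was 0.810 between replicates 1 and 3 (4434 peaks), 0.722 between 2 and 3 (4412 peaks) and 0.693 between 1 and 2 (4390 peaks). These values are across peaks, which are not independent replicates. The reproducible set was itself derived from these replicate lists by the IDR step. The shares and rho values in this set are therefore no independent measure of agreement.

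E(spl)mgamma-HLH peaks lay mainly at promoters and seldom in coding sequence or UTRs outside them. Exon sequence within 500 bp of a TSS was counted as promoter. Promoters held 2264 summits, 50.04% of the set (48.6 to 51.5%), against 13.4% for shifted summits, a 3.74-fold excess. Coding sequence held 10 summits (0.221%) against 13.7%, and 3' UTRs 26 (0.575%) against 4.44%. Introns held 1611 summits (35.6% against 40.2%), intergenic sequence 595 (13.2% against 27.5%) and 5' UTRs 18 (0.398% against 0.778%). The adjusted permutation p was 0.0024 for each class except 5' UTRs (0.00599), and the unadjusted 0.002 behind it is the smallest two-sided p that the shifts can give. The median distance from a summit to the nearest protein-coding TSS was 595.5 bp (quartiles 119.75 and 3553 bp), and 443 summits (9.79%) lay over 10 kb away. The promoter excess was 5.98-fold with promoters of 200 bp, where the intron share no longer fell (1.00-fold, adjusted permutation p = 0.929). The intron call was also lost in the looser set (0.965-fold), the 5' UTR call in the upper part of the set (0.561-fold), and coding sequence went from 0.0161 of the shifted share to 0.0102 without replicate 2 and 0.0442 in the looser set.

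**Figure D1:**
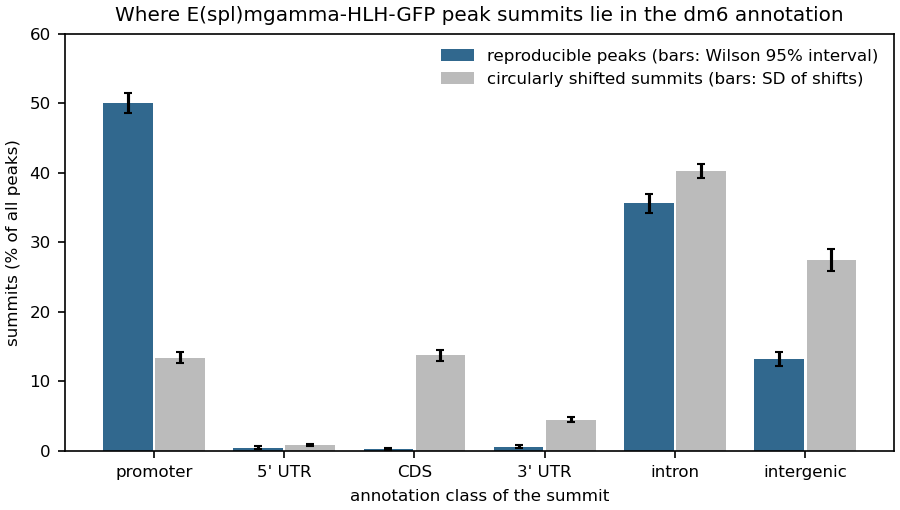
Share of reproducible summits (%) in each annotation class beside the mean share of shifted summits, with Wilson 95% intervals for the former and the SD over shifts for the latter as bars. Promoters stand at 50.04% against 13.4%, while coding sequence stands at 0.221% against 13.7%.

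The Enhancer of split complex itself carried 13 reproducible peaks in 45.388 kb (3R:25996621 to 26042008). The highest of them, named after its values were seen, was intergenic, -1789 bp from the TSS of E(spl)malpha-BFM (3R:26008959 to 26009239), with rank 244 in the set and 337, 224 and 235 in replicates 1 to 3; it lay outside the territory of every listed gene. Of its 7 bHLH repressor genes, which mediate the transcriptional response to Notch, 4 had a peak in the gene or 1 kb upstream, against 0.890 expected (4.49-fold, adjusted permutation p = 0.0457). The best summits of all 4 were in promoters. The best peak of E(spl)m3-HLH lay at -438 bp (3R:26021193 to 26021576, rank 704), that of E(spl)mbeta-HLH at -79 bp (rank 980), that of E(spl)mdelta-HLH at -314 bp (rank 1213) and that of E(spl)m7-HLH at -276 bp (rank 2532). The peak counted for E(spl)mdelta-HLH lay slightly closer to the TSS of the divergent gene CG43116 (-311 bp). Members without a reproducible peak in the gene or 1 kb upstream, named after their values were seen, were E(spl)m5-HLH, E(spl)m8-HLH and the tagged gene E(spl)mgamma-HLH. The matching peaks ranked 991, 654 and 506 in replicates 1 to 3 at E(spl)m3-HLH, 4702, 174 and 2436 at E(spl)mbeta-HLH, 1340, 875 and 2130 at E(spl)mdelta-HLH, and 15645, 1066 and 2545 at E(spl)m7-HLH. Replicate 2 had 17 of its top peaks in the complex, replicate 1 had 6 and replicate 3 had 10. The list call was lost without replicate 2 (2 members, 2.63-fold, adjusted permutation p = 0.627), without replicate 3 (2 members, 3.02-fold, adjusted permutation p = 0.456) and with the top peaks of replicate 1 alone (2.24-fold). It was also lost in the upper part of the set (5.52-fold, adjusted permutation p = 0.141), with a TSS within 1 kb (4.404-fold, adjusted permutation p = 0.0502) and by nearest TSS (4.28-fold, adjusted permutation p = 0.161). The call held in the looser set (4.28-fold, adjusted permutation p = 0.0030) and without replicate 1 (5.50-fold, adjusted permutation p = 0.0300). It also held with the top peaks of replicate 2 alone (5.89-fold, adjusted permutation p = 0.0040), of replicate 3 alone (4.53-fold, adjusted permutation p = 0.0450) and against circular shifts (10.03-fold, adjusted permutation p = 0.0300). In simulation, 7-gene lists with 60% of members bound were recovered in 0 of 50 draws. Those lists were not matched to the territory length of these genes, so the simulation gives no recovery rate for this list. Whether the transgenic line carries extra copies of this locus is not known here. Such copies were not tested as a cause of the excess.

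**Figure D2:**
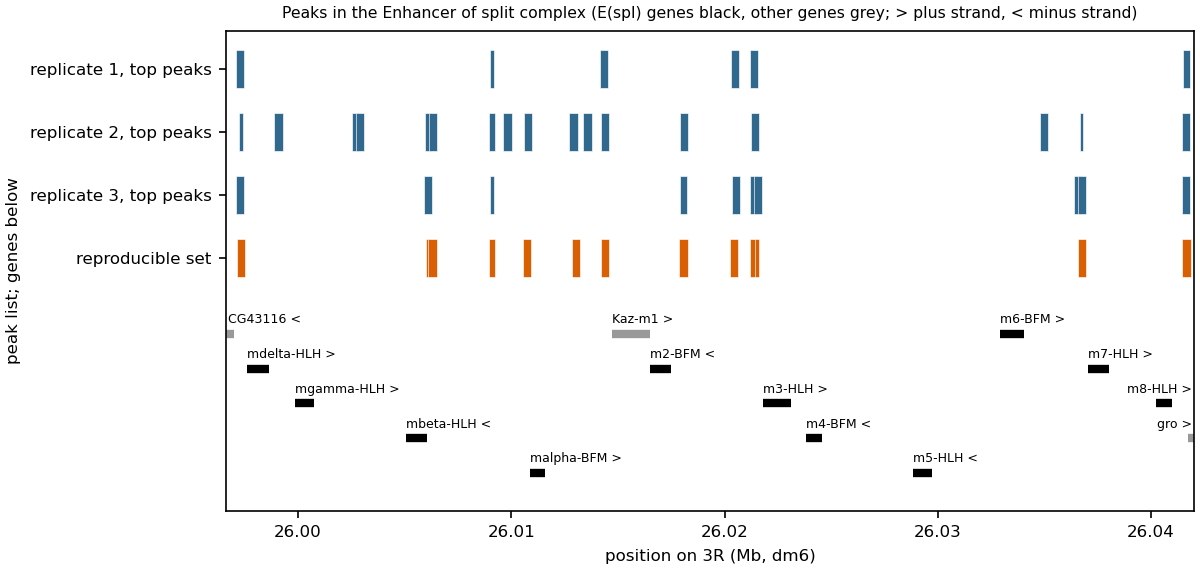
Positions of peaks in the Enhancer of split complex (x axis, Mb on 3R, dm6) for the top peaks of each replicate and for the reproducible set, with genes and their strand drawn to scale underneath. The reproducible set has 13 peaks, and the top peaks number 6, 17 and 10 in replicates 1, 2 and 3.

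Among Bearded family genes, which encode inhibitors of the Neuralized ubiquitin ligase, 2 of 8 had a peak (0.992 expected, adjusted permutation p = 0.702). They were E(spl)malpha-BFM (-146 bp, rank 3554) and E(spl)m2-BFM (-604 bp, rank 2921, inside a noncoding gene). No peak in the replicate 1 list matched the first of these. Of the 10 proneural bHLH activators and partners, 2 had a peak (2.11 expected, adjusted permutation p = 1): da, the shared partner of proneural proteins (-111 bp, rank 2090), and emc, which encodes their inhibitor (74 bp, rank 3764, with no matching peak in the replicate 3 list). Of 6 other bHLH-Orange repressor genes, cwo had an intronic peak (5627 bp from its TSS, rank 1605) and no call was made (1.76 expected, adjusted permutation p = 0.919).

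Of 18 Notch pathway genes, 10 had a peak against 6.90 expected (1.45-fold), which did not pass the test (adjusted permutation p = 0.358). The highest was at gro, the corepressor recruited by Hairy/E(spl) proteins, at -127 bp from a TSS (3R:26042365 to 26042651), with rank 105 in the set and 140, 123 and 102 in the replicates. The Notch inhibitor numb had a promoter peak at -145 bp with rank 173, and mam, a coactivator of Notch, had 8 peaks, the best of them intronic with rank 453. The receptor gene N had an intronic peak 27699 bp from its TSS (rank 940), and neur had an intronic peak at 1705 bp (rank 712). The secretase subunit genes aph-1 (-298 bp, rank 565), Nct (-1000 bp, rank 1407) and pen-2 (-166 bp, rank 2944) and the glycosylation genes fng (-690 bp, rank 2300) and O-fut1 (-33 bp, rank 3001) made up the rest. Of these 10 genes, 5 owned the TSS nearest to their best summit. At Nct the nearest was that of CG7006 (-26 bp), at pen-2 that of Ote (-96 bp), at aph-1 that of Snx21 (-270 bp), at mam that of CG18371 and at N that of CG18508.

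Cytoplasmic ribosomal protein genes carried peaks far more often than matched genes. Of 92 such genes 54 had a peak (58.7%), against 16.7 expected, a 3.24-fold excess (adjusted permutation p = 0.0015; the unadjusted 0.0002 is the smallest that 10000 random lists can give). For 53 of the 54 the best summit was in a promoter, and for 42 the nearest protein-coding TSS was their own. The highest-ranked were RpL32 (-196 bp, rank 134, with CG7943 nearer at -113 bp), RpS27 (-23 bp, rank 165), RpL34b (-70 bp, rank 180) and RpL7 (29 bp, rank 294). Against circular shifts, which follow the density of genes less closely, the excess was 7.97-fold.

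EGFR pathway genes also carried peaks more often, mostly in introns, while odorant and gustatory receptor genes were nearly free of them. Of 10 EGFR pathway genes 9 had a peak (4.79 expected, 1.88-fold, adjusted permutation p = 0.0457), and kek1, named after its values were seen, had none. The best were in introns of aos, which encodes a secreted EGFR inhibitor (3087 bp, rank 157), of S, which encodes the ligand trafficking protein Star (1855 bp, rank 182), and of aop, which encodes an ETS repressor (rank 557), and at the promoter of spi, which encodes an EGFR ligand (-176 bp, rank 246). S and spi each held 5 peaks and aop held 4. Of 119 receptor genes 3 had a peak against 25.1 expected (0.1195-fold, adjusted permutation p = 0.0015). These were Or88a, Or9a and Gr32a, and in each case another gene's TSS was nearer (CG12402 at -460 bp, Neb-cGP at -74 bp and Idua at -157 bp). The EGFR call was lost without replicate 1 (2.00-fold, adjusted permutation p = 0.0696), without replicate 2 (1.65-fold, adjusted permutation p = 0.369), without replicate 3 (1.76-fold, adjusted permutation p = 0.304), with replicates 1 or 3 alone (1.45-fold and 1.65-fold), with the upper or the looser set (1.92-fold and 1.35-fold) and with TSS-based assignment (1.57-fold within 1 kb, 1.76-fold by nearest TSS). The EGFR call held with the top peaks of replicate 2 alone (1.93-fold, adjusted permutation p = 0.0367) and against circular shifts (2.28-fold, adjusted permutation p = 0.0300). The receptor call was lost against circular shifts (0.308-fold, adjusted permutation p = 0.0699).

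The other developmental lists did not pass the test. Sensory organ and neuronal genes had a peak in 9 of 13 (6.30 expected, adjusted permutation p = 0.358), led by the pan-neuronal RNA-binding protein gene elav at -263 bp (rank 98; 136, 109 and 81 in the replicates), then ct (rank 1049), lola (rank 1133) and jing (rank 1221). Neuroblast and temporal factors had a peak in 4 of 20 (7.51 expected, adjusted permutation p = 0.349): brat, a translational repressor of neural progenitors with 4 peaks (best rank 135), grh (rank 866), insc (rank 2206) and nab (rank 3441). Of 17 segmentation genes, wg alone had a peak (6490 bp from its TSS, rank 3832) against 4.97 expected (unadjusted permutation p = 0.0456, adjusted 0.137); the adjusted p was 0.022 with the top peaks of replicate 3 alone. Hox genes had a peak in 3 of 8 (4.19 expected, adjusted permutation p = 0.715), namely Antp with 7 peaks, Abd-B (rank 2659) and Dfd (rank 3377).

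Mesoderm and muscle regulators had a peak in 6 of 11 (4.31 expected, adjusted permutation p = 0.643). The best were zfh1 (rank 225), Mef2, a muscle differentiation factor with 5 peaks (best rank 543, in the 5' UTR), how (rank 811) and tin, a heart and visceral mesoderm factor (-178 bp, rank 982). Signalling genes of the Wg, Hh, Dpp and JAK/STAT pathways had a peak in 15 of 25 (11.4 expected, adjusted permutation p = 0.358), led by the Wg receptor gene fz with 7 peaks (best rank 143, 29733 bp from its TSS), Mad (rank 271), sog (rank 396) and Socs36E (rank 839). Cell cycle genes had a peak in 5 of 10 (3.66 expected, adjusted permutation p = 0.702), namely trbl (rank 1016), CycE (-419 bp, rank 1216), E2f1 (rank 2185), Cdk1 (-227 bp, rank 2247) and, chosen after its values were seen, CycB (rank 3081). In all, 3680 of 13945 protein-coding genes (26.4%) had a peak in the gene or 1 kb upstream.

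**Figure D3:**
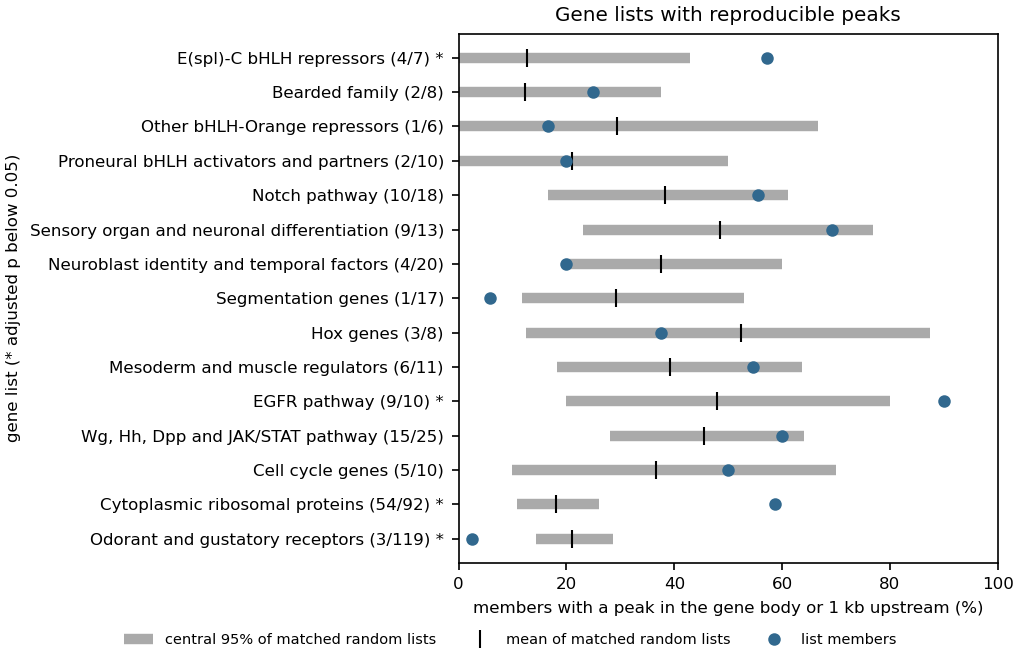
Members of each of the 15 gene lists with a reproducible peak (%, points), with the mean (ticks) and central 95% (grey bars) of random lists matched on gene length. Ribosomal proteins stand at 58.7% and receptors at 2.52%, and asterisks mark an adjusted p below 0.05.

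Sites bound by Hairy/E(spl) proteins in other assays, the E-box CACGTG and the class C site CACGCG, were less common at summits than in flanks, and the promoter element TATCGATA bound by DREF was more common. CACGTG stood in 37 summit windows (0.818%) and 1.86% of flanking windows (0.440-fold, exact adjusted p = 3.92e-05, exact McNemar test), and CACGCG in 53 (1.17%) against 2.87% (0.408-fold, exact adjusted p = 5.31e-08). The random sides drawn gave a high flanking share of CACGTG: over 1000 draws the central 95% ran from 1.28 to 1.79%, and both sides together gave 1.54% (0.532-fold). With all flanks on the left or all on the right, alternatives chosen after seeing the data, CACGTG was at 0.552-fold (exact adjusted p = 0.00770) and 0.514-fold (exact adjusted p = 0.00205). Of the 10 E-box hexamers 7 were lower at summits, 0 were higher and 3 did not pass, among them CATATG (3.89% against 3.25%, exact adjusted p = 0.153). Of the 4 N-box hexamers CACCAG (0.531-fold) and CACGAG (0.508-fold) were lower, CACAAG did not pass (exact adjusted p = 0.189, but 0.0127 with all flanks on the left), and CACTAG was higher, in 167 windows (3.69%) against 1.77% (2.09-fold, exact adjusted p = 8.09e-08). TATCGATA stood in 88 summit windows (1.95%) and 9 flanking windows (0.199%), a 9.78-fold excess (exact adjusted p = 4.01e-16). GAGAG was lower (9.86% against 14.5%), and the Su(H) site (0.973% against 1.26%, exact adjusted p = 0.245), CAGGTA (exact adjusted p = 0.0817) and GGCACGTG (5 windows against 12, exact adjusted p = 0.179) did not pass.

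Summit windows were richer in A and T, with a mean GC content of 34.7% (SD 8.81) against 44.2% (SD 10.2) in flanks. Of all hexamers searched, 527 were higher and 938 lower at summits, led by TTAAAA (31.0% against 13.5%) and CTCCTC (0.995% against 6.08%). The lower share of CACGTG was not called without replicate 1 (0.604-fold, exact adjusted p = 0.0659), without replicate 2 (0.625-fold, exact adjusted p = 0.0765), in promoter peaks alone (0.619-fold, exact adjusted p = 0.114) or against dinucleotide shuffles of the same windows (0.841-fold, exact adjusted p = 0.618), and turned to 1.40-fold (exact adjusted p = 0.613) against nearby windows of the same GC count. CACGCG was not called against the shuffles (0.757-fold, exact adjusted p = 0.226), and no fixed motif was called lower against them. Called higher against shuffles were CAGCTG (2.32-fold), CAAGTG (1.33-fold), CATATG (1.40-fold), GAGAG (1.24-fold), CACTAG (1.49-fold) and TATCGATA, whose fold was above that against flanks. Against windows of the same GC count CAGCTG was called higher (1.39-fold), and GAGAG was not called (1.09-fold, exact adjusted p = 0.603). CACTAG stayed higher against these windows (2.09-fold, exact adjusted p = 5.91e-07). TATCGATA also stayed higher there, at a smaller fold than against flanks (4.47-fold, exact adjusted p = 4.51e-10). With flanks 1000 bp away TATCGATA was at 5.18-fold and CACTAG at 2.61-fold, both still called. The excess of TATCGATA was 21.3-fold in promoter peaks and absent from other peaks (1.00-fold), and CACTAG was 3.16-fold in promoter peaks and not called in others (1.57-fold, exact adjusted p = 0.0587).

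**Figure D4:**
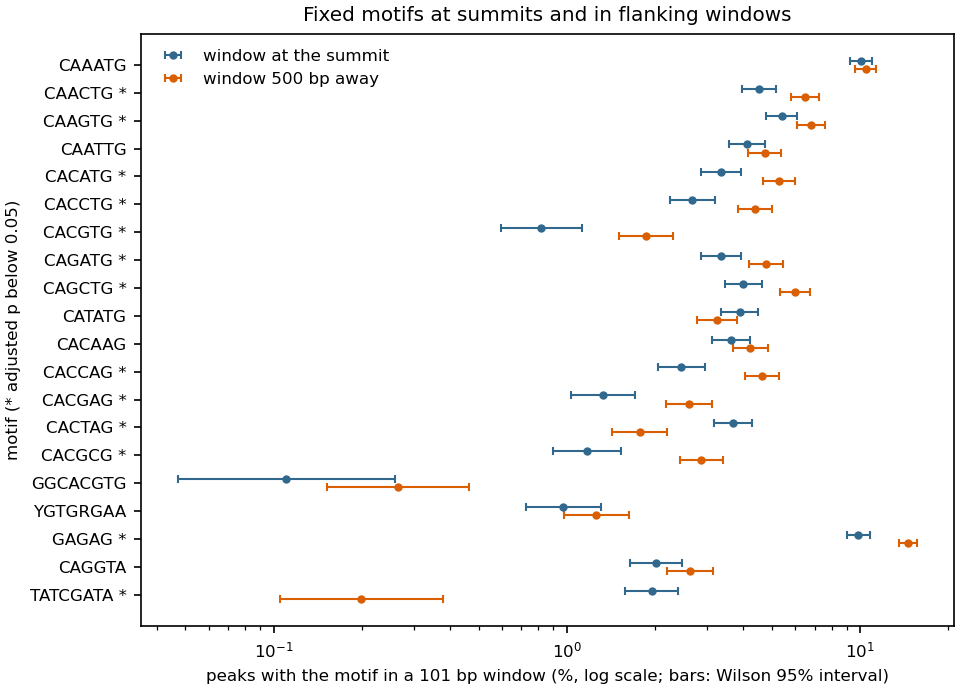
Share of windows (%, log axis) holding each of the 20 fixed motifs at reproducible summits and in flanking windows, with Wilson 95% intervals. TATCGATA stands at 1.95% against 0.199%, CACTAG at 3.69% against 1.77% and CACGTG at 0.818% against 1.86%.

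Peaks with a Hairy/E(spl) site were not shown to rank apart from the rest. The 37 peaks with CACGTG had a median rank of 2164 against 2264 for peaks without (difference -100, adjusted permutation p = 0.790, permutation test), and the 53 with CACGCG 2667 against 2260 (difference 407, adjusted permutation p = 0.561). The 475 peaks with any N-box had a median rank of 2314 against 2257 (difference 57, adjusted permutation p = 0.790). Over 10 equal rank bins the share ran from 0.221 to 1.33% for CACGTG, from 0.442 to 1.77% for CACGCG and from 7.74 to 12.6% for N-boxes. CACGTG, CACGCG or an N-box stood in 550 summit windows (12.2%). The few peaks with CACGTG or with CACGCG limit the precision of the rank comparison for these motifs.

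Relative to their share of TSSs, the X and 3L held more peaks and 2R and chromosome 4 held fewer. The X had 866 peaks, 36.8 per Mb (exact Poisson 95% interval 34.4 to 39.3), 1.13 times its share of TSSs (exact adjusted p = 0.000339, exact binomial test). Chromosome 4 had 13 peaks, 9.64 per Mb (5.13 to 16.5), 0.390 times its share (exact adjusted p = 0.000339), and 2R had 784, 31.0 per Mb (28.9 to 33.3), 0.847 times (exact adjusted p = 6.57e-07). Arm 3L had 946 peaks (1.08 times, exact adjusted p = 0.0126), and 2L (843 peaks, 35.9 per Mb, interval 33.5 to 38.4) and 3R (1072 peaks) did not pass (exact adjusted p = 0.889 for each). The 3L call was lost without replicate 1 (1.07 times), without replicate 2 (1.05 times) or without replicate 3 (1.07 times) and turned against arm length (0.996 times). In the upper part of the set X (1.09 times), 3L (1.06 times) and 4 (0.539 times) were not called.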

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

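The comparisons above used the main chromosome arms in dm6, on which all dm6 peaks lay. The dm3 lists also held peaks on the heterochromatic and unplaced sequences of that build, which no comparison used, and a signal in such unused data is what set these values apart. Replicate 1 had 261 of these peaks, replicate 3 had 229 and replicate 2 had 23. Those with a q-value below 0.05 numbered 12 in replicate 1, 9 in replicate 3 and 9 in replicate 2. Most of the listed peaks, and nearly all of those in replicates 1 and 3, thus did not pass that threshold. In replicate 1 the 2RHet sequence held 109 of all listed peaks off the arms, 3LHet 67 and 3RHet 49, of which 4, 3 and 2 had a q-value below 0.05. In replicate 3 these held 91, 62 and 38 (3, 3 and 1 below 0.05), and in replicate 2 they held 1, 3 and 4 (1, 2 and 0). Uextra held 8 in replicate 2 (5 below 0.05) against 4 in replicate 1 and 6 in replicate 3 (0 below 0.05 in each), and XHet held 8, 6 and 7 in replicates 1 to 3. The dm3 reproducible set had 1 such peak, on 2RHet, with rank 1611. The difference between replicates was not tested, no control library was analysed here, and no biological explanation was tested.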

How the results depend on the processing

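Windows matched on GC count, flanks all on 1 side, the top peaks of single replicates, and leaving out replicates for shared peaks and ranks were chosen after seeing the data; the other alternatives were set before. Over 57 results and 612 recomputed values, 526 kept their side of the threshold or stayed within the allowed spread, and 27 results had all their alternatives on the same side. Of the other values, 49 lost a call, 8 gained a call and 13 moved beyond the allowed spread. Another 16 changed direction with the main or the recomputed value called, none of them when a replicate was left out. Some results not called in either also turned. Peaks shared between replicates, the promoter and ribosomal protein excesses and the 2R deficit kept their side of the threshold in each alternative run. The upper set held 2262 peaks, the looser set 9048, and the sets without replicate 1, 2 or 3 held 3394, 3572 and 3346. The files give no reads, so what depth limits cannot be computed. Except where fewer peaks entered, the cause was not tested for the changes that follow.

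With a replicate left out only 1 pair remained, so rho was that of the pair, from 0.693 to 0.810, the values given above. In the upper set the 5' UTR fold was 0.561, the E(spl) list 5.52, the EGFR list 1.92, X 1.09, 3L 1.06 and chromosome 4 0.539 times the expectation, none still called, and 1 list stayed higher. In the looser set introns (0.965) and EGFR genes (1.35) lost their call. With promoters of 200 bp introns were at 1.00. Without a replicate the folds ran from 0.509 to 0.625 for CACGTG, 2.63 to 5.50 for the E(spl) list, 1.65 to 2.00 for EGFR genes and 1.05 to 1.07 for 3L, and the lists called higher numbered 1 to 2. Against dinucleotide shuffles CACGTG (0.841) and CACGCG (0.757) lost their call. CAACTG (1.11), CAAGTG (1.33), CACCTG (1.32), CAGATG (1.06), CAGCTG (2.32), CACCAG (1.01) and GAGAG (1.24) turned from lower to higher. Of these, CAAGTG, CAGCTG and GAGAG went from called lower to called higher. In all, 6 motifs were called higher against shuffles and 0 lower. Against windows of the same GC count CACGTG (1.40), CACCTG (1.11), CAGATG (1.10), CAGCTG (1.39), CACCAG (1.06), CACGAG (1.06) and GAGAG (1.09) turned. Of these only CAGCTG was called higher, and 2 motifs were called lower. CACTAG (2.09) and TATCGATA (4.47) stayed called higher. With all flanks on the left or right CACGTG was at 0.552 and 0.514, still called. In promoter peaks CACGTG was at 0.619. In other peaks CACTAG (1.57) and TATCGATA (1.00) lost their call and 0 motifs were higher. With a TSS within 1 kb the E(spl) list was at 4.404 and EGFR genes at 1.57, by nearest TSS at 4.28 and 1.76, and with replicate 1 alone at 2.24 and 1.45, none called, each time with 1 list higher. With replicate 3 alone EGFR genes were at 1.65 and 2 lists were lower. Against circular shifts receptors were at 0.308 and 0 lists were lower, and against arm length 3L was at 0.996.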

Other observations

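The gene families, noncoding genes, the side of the TSS, the 8-mers and peaks of single replicates were examined after seeing the data, as were the test of extra gene copies and the GC-matched test of CACGCG; the shuffles were set before, but their use to weigh CACGCG was chosen after. Mitochondrial ribosomal protein genes, like the cytoplasmic ones, carried reproducible peaks more often than matched genes: 29 of 73 against 10.4 expected (2.79-fold, adjusted permutation p = 0.0004). Proteasome subunit genes (12 of 43, adjusted permutation p = 0.281) and translation initiation factor genes (13 of 44, adjusted permutation p = 0.783) did not pass. Cuticle protein genes had 0 of 110 against 18.5 expected, cytochrome P450 genes 4 of 83 against 21.1 (Cyp310a1, Cyp317a1, Cyp4d20 and Cyp6u1), ionotropic receptor genes 1 of 60 against 14.9 (Ir60e), each with an adjusted permutation p of 0.0004, and odorant binding protein genes 2 of 51 against 7.22 (Obp83g and Obp99b, adjusted permutation p = 0.0486). Glutathione S transferase genes (3 of 35, GstE13, GstT4 and GstZ2) did not pass (adjusted permutation p = 0.281). The unadjusted p behind 0.0004 is 0.0002, the smallest that the random lists can give. Random lists draw genes singly, so where family members are neighbours in the genome these p-values can be too small. The families were not tested against circular shifts, where the odorant and gustatory receptor list lost its call (0.308-fold, adjusted permutation p = 0.0699).

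Among noncoding genes, 189 of 3261 ncRNA genes had a summit within 500 bp of a TSS, 1.75 times the mean of shifted summits (adjusted permutation p = 0.00799). The promoter class as a whole, counted in summits and not in genes, was at 3.74-fold against shifted summits. The value for ncRNA genes thus shows no excess beyond that of promoters in general. Of 32 snRNA genes 5 had one (4.79-fold, adjusted permutation p = 0.032), namely 7SKa, U1:95Ca, U5:35D and the neighbouring U6:96Ab and U6:96Ac. The 290 tRNA genes (12 with a summit, adjusted permutation p = 0.797) and the 269 snoRNA genes (8, adjusted permutation p = 1) did not pass. Of 2149 summits within 500 bp of the nearest protein-coding TSS, leaving out 1 that lay on it, 1872 (87.1%, Wilson 95% interval 85.6 to 88.5%) lay upstream of the nearest protein-coding TSS, against 44.9% (SD 2.16) of shifted summits (permutation p = 0.002, the smallest the shifts can give). Their median position was -102 bp, with quartiles at -186 and -45 bp.

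Of 32896 8-mers compared between summit windows and dinucleotide shuffles, 205 were more common at summits and 23 less. ATCGATAG, which overlaps the DREF element, stood in 99 windows against 8 shuffled, in 4.24% of promoter peaks and 0.133% of other peaks. CAACACTG stood in 97 against 16, in 3.84% of promoter and 0.442% of other peaks, and GGTCACAC in 39 against 4. CACTGTGC (89 against 10) and CACAGTGG (79 against 7) were spread over promoter and other peaks (2.08 and 1.86%, 2.03 and 1.46%). CACTGAGA (73 against 9) stood in 0.574% of promoter and 2.65% of other peaks, GAGAGAAA (79 against 16) in 0.618 and 2.88%, and AGATGGCG (58 against 5) in 0.928 and 1.64%. None of the 8-mers named here holds CACGTG, CACGCG or an N-box. They were picked from the 205, and the rest were not searched for these sites. The lowest p belonged to AAATATAT (265 windows against 86 shuffled). As a fixed motif, the N-box CACTAG was called higher against dinucleotide shuffles (1.49-fold). Peaks of single replicates were top peaks that shared no base with a top peak of either other replicate, a stricter rule than the summit rule above. The 673 of replicate 2 had a mean GC content of 40.5% (bootstrap 95% interval 39.6 to 41.3%) and GAGAG in 19.2%. The 511 of replicate 1 had 37.3% GC and GAGAG in 10.96%, and the 458 of replicate 3 had 34.5% GC and GAGAG in 11.6%.

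The lower share of CACGTG and CACGCG at summits was weighed against base composition, and no biological explanation was tested. Against nearby windows of the same GC count, found for 3952 peaks, the CACGTG share was 1.40 times as high at summits (bootstrap 95% interval 0.838 to 2.38), so GC content may account for its lower share. For CACGCG the matched ratio stayed at 0.603 (0.411 to 0.857), which argues against GC content as the whole cause, while against dinucleotide shuffles it was 0.757 (0.527 to 1.07), so dinucleotide content stays open. CACGTG was 1.13 times as common 100 to 250 bp from summits as 500 to 1000 bp away (0.986 to 1.29), and whether sites lie beside the summit cannot be told apart from no such shift, because the interval includes 1.

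Peaks at ribosomal protein genes might be signal that follows transcription at any active promoter. Among the 2150 peaks within 500 bp of a protein-coding TSS (the 2264 promoter peaks also count noncoding TSSs), the 44 at these genes had a median rank of 1016.5 against 1078.5 for the rest, a difference of -62 (permutation p = 0.703), so binding and such signal cannot be told apart: no expression data and no control library were analysed here. No biological explanation was tested.

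Peaks of the Enhancer of split complex ranked higher in replicate 2: among 4360 peaks matched in all replicates, the 11 in the complex had a median rank of 3372 in replicate 1, 1041 in replicate 2 and 2442 in replicate 3, and 8 of them ranked higher in replicate 2 than in each other replicate. Their median gain over the mean of the other replicates was 1197.5 places, outside the -556.5 to 566.5 of random sets of the same GC content (permutation p = 0.0006). It was 1025 places over 10 peaks (permutation p = 0.0014) when the replicate 2 peak matched by 2 overlapping peaks at E(spl)m3-HLH counted once. The random sets were matched on GC count and not on rank. Replicate 2 was taken up after its peaks in the complex were seen, which the p-values leave out of account. The random sets also drew single peaks across the genome, while the complex peaks are neighbours in 1 locus whose ranks may move together. The range can thus be too narrow and the p-values too small, so the test does not settle whether a GC bias of replicate 2 is the cause. The labels give all replicates the same line, so extra copies of the locus would act in each, but top peaks within 20 kb of E(spl)mgamma-HLH numbered 4, 14 and 5, the lowest at percentile 79.5 of all genes. This argues, from values already seen, against copies alone as the cause of a difference between replicates, not against copies being present. No biological explanation was tested, and the age mix of the embryos or the tagged protein level, which may differ between collections, stay open.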
